A study of Rattus norvegicus with 11 samples.

How the data were processed

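Pancreatic islets of Sprague-Dawley rats were profiled by single-end small RNA sequencing, with 5 libraries from 10-day-old pups and 6 from 3-month-old males. Per the labels' protocols, total RNA was extracted with Trizol and libraries were built with an Illumina TruSeq small RNA kit from total islet RNA, with adapter ligation, limited PCR and size selection. Ligation and PCR favour some miRNA sequences, so levels of different miRNAs within a library are less comparable than 1 miRNA between libraries. No molecular identifiers are stated, so counts are reads and not molecules.

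The authors deposited raw read counts per mature miRNA arm and locus, on Rnor_5.0 per the file headers and the submitters' processing notes (rn5). These notes also name edgeR and DESeq, with no role or version. The aligner, the counting rules and the miRNA annotation are not given in the sources used here. The series-wide table was tested against the per-library tables and held the same counts. It has 950 rows, of which 7 repeat another row's name and place, and 43 names occur at more than 1 locus. Features carry a sense or antisense tag. Whether reads of multi-copy miRNAs were split or repeated across loci is not stated, so such members are uncertain. Numbered loci of a miRNA keep separate names, so counts of list members can hold the same arm more than once.

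Each mature name entered once, with the highest count over its rows in each library, a rule fixed before the data were examined; 898 features resulted. Antisense features kept their tag and belonged to no list. Of 227 features with an Ensembl transcript identifier, 0 matched the RefSeq gene table (GRCr8), which was used only for names and for which miRNA genes overlap. Coordinates are those of the files, and no genome sequence was used.

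Counts were analysed in R 4.3.3. edgeR 4.0.16 filtered features by expression (filterByExpr with the age group), computed TMM factors, and fitted a robust quasi-likelihood model of age (adult minus P10). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM are counts scaled to a fixed total by the TMM-adjusted library size, and standard errors of log2 fold changes were derived from the quasi-likelihood statistic. Log2 CPM used a prior count of 2. The 23 miRNA lists, 15 of programs or families and 8 of markers of other cell types, were fixed before the data were examined. The 17 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. With an estimated correlation 0 of the 9 lists called with the preset correlation held. Library composition, on library totals without TMM factors, was compared by two-sided exact permutation over 462 splits. Arm usage was tested with limma on the log2 ratio of 5p to 3p CPM.

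The miRNAs named in the text were chosen by a rule fixed before the data were examined. It took the 10 most abundant by mean CPM. It took the 10 largest rises and the 10 largest falls among miRNAs that passed the test, averaged at least 50 CPM and did not overlap between ages. From each list it took the 2 members with the highest mean CPM and the 2 with the smallest p, and for arm usage the 5 precursors with the smallest p. Names outside the rule are marked as such, apart from the arms of precursors named under it.

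Library totals ranged from 1432929 to 4483017 counts. At this depth 1 count corresponds to less than 1 CPM in every library, and miRNAs of a few CPM rest on few reads. No pair of libraries of the same age agreed within sampling noise (lowest chi-square per degree of freedom 12.1), which does not show that they are independent; each counted as 1 replicate, as the labels call them biological replicates. Labels do not say whether a library pools several animals. Pup sex was not used here.

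The edgeR step was tested on simulated counts with known changes, in which 444 miRNAs passed the filter. It recovered 55.1% of the miRNAs changed 1.5-fold, 89.8% of those changed 2-fold, 95.8% of those changed 4-fold and 100% of those changed 8-fold, and called 2 of 253 unchanged miRNAs. The arm ratio test recovered 21 of 28 precursors changed 3-fold and called 0 of 114 unchanged among 142. The camera step, over 449 miRNAs, called the 1 list changed 2-fold and 0 of 16 others. The simulated miRNAs varied independently, while the estimated correlations of the tested lists ran from 0.07 to 0.80. The simulation therefore could not show false list calls that come from correlated members.

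Alternatives planned before the data were examined were DESeq2's size factors, library totals alone, upper-quartile scaling, scaling without the most abundant miRNA, no filter, a mean CPM of at least 10, limma-voom, DESeq2 1.42.0, the replicate number as a block, summed rows, and leaving out each library. For the lists they were an estimated correlation, fry and a single arm of each name. For arm usage they were a prior count of 0.5 and a mean CPM of at least 10 for both arms, and for composition a detection limit of 10 counts. Added after seeing the data were a mesenchymal covariate, thinning all libraries to 1430412 counts, leaving out Ensembl-only features, and naming antisense features by the overlapping RefSeq gene, with a preset and an estimated correlation.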

Results

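Small RNA from isolated pancreatic islets of Sprague-Dawley rats was sequenced at 2 ages, postnatal day 10 (P10, suckling pups, 5 libraries) and 3 months (adult males, 6 libraries). Islets are the endocrine cell clusters of the pancreas, in which insulin-secreting beta cells predominate. The labels call the libraries biological replicates, and the sex of the pups was not used here, so age and sex could not be separated. The P10 libraries held 2468720, 1599157, 3350533, 3024258 and 4483017 miRNA counts (replicates 1, 3, 4, 5 and 6). The adult libraries held 1432929, 2722608, 1615881, 1553517, 2847837 and 2060534 counts (replicates 1 to 6). Each feature was a mature miRNA arm with its position in Rnor_5.0. After 1 entry per name was kept, 898 features remained, and 457 passed the abundance filter and were tested.

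Adult islet libraries were dominated more strongly by miR-375-3p, the leading miRNA of pancreatic endocrine cells, which restrains insulin secretion and is needed for normal islet cell mass. This single miRNA took 26.5% ± 1.99 (SD, n = 6) of the counts in adults and 15.97% ± 3.34 (SD, n = 5) at P10, a difference of 10.5 percentage points (two-sided exact permutation test over 462 splits, p = 0.00216, adjusted p over the 3 composition measures = 0.00216). The 10 most abundant miRNAs held 73.8% ± 0.611 of the adult counts (SD, n = 6) and 68.0% ± 0.916 of the P10 counts (SD, n = 5, exact permutation p = 0.00216). This difference, 5.78 percentage points, is smaller than that of miR-375-3p, which is among the 10. The rest of the 10 thus took a smaller share in adults. Fewer miRNAs reached 1 CPM in adults, 537 ± 5.33 (SD, n = 6), than at P10, 569.6 ± 11.2 (SD, n = 5; exact permutation p = 0.00216). For each of the 3 measures the groups did not overlap, and 0.00216 is the smallest p these splits can give. With a detection limit of 10 counts, which depends on depth, 419 ± 24.4 miRNAs were detected in adults (SD, n = 6) and 476.4 ± 35.8 at P10 (SD, n = 5), a difference of -57.4 against -32.6 (exact permutation p = 0.0216). By that limit the groups overlapped, as P10 replicate 3 (415) lay below adult replicates 2, 5 and 6. Counts over these features averaged 2034290 in adults and 2974789 at P10 (exact permutation p = 0.0996).

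The main comparison asked which islet miRNAs differ between suckling pups and mature animals. The miRNA profile differed broadly: the first principal component held 61.0% of the variance and separated the ages. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 97 miRNAs were higher and 135 lower in adults among 457 tested. The change was at least 2-fold for 36 of the higher and 84 of the lower miRNAs. The CPM ranges of the groups did not overlap for 137 of the 457 tested miRNAs, where chance alone gives 0.433%. All 137 were among the 232 differentially expressed miRNAs. Fold changes are relative to the TMM scaling. With library totals alone the median of all miRNAs shifted by -0.26 (log2), and 54 miRNAs were higher and 187 lower (22.4% of calls higher, against 41.8%). With upper-quartile scaling it shifted by 0.16, with 127 higher and 103 lower (55.2% higher). With the mean level of the mesenchymal marker list as a covariate, chosen after seeing the data, 33 miRNAs passed, 27 of them among the 232; this covariate correlates with age at -0.87. Of the 205 calls that ended, 145 kept at least 50% of their log2 change, 49 kept less and 11 changed direction. Over these 205 the median size of the log2 change went from 0.98 to 0.69 and the median SE from 0.22 to 0.42.

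**Figure D1:**
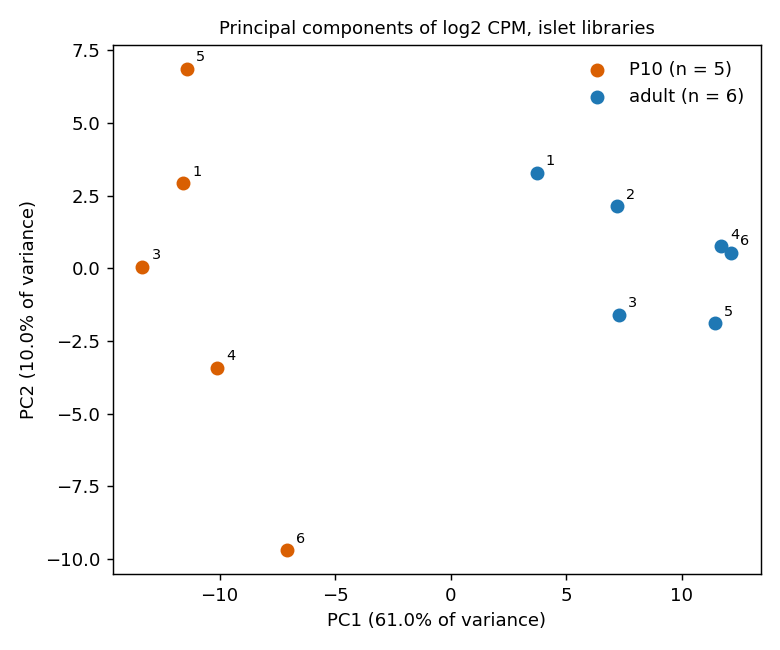
Principal components of the log2 CPM of 457 miRNAs in 11 islet libraries. The first axis (61.0% of the variance) separates the 5 P10 libraries on the left from the 6 adult libraries on the right, and the second axis holds 9.96%. Numbers beside the points are replicate numbers.

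Among the 10 most abundant miRNAs, miR-375-3p, miR-27b-3p, miR-22-3p and miR-141-3p rose, and miR-10a-5p and miR-10b-5p, from the Hox clusters, fell. miR-375-3p (chromosome 9, 81930305 to 81930326, minus strand) rose 2.01-fold, from 143108 ± 21141 CPM at P10 (SD, n = 5) to 287796 ± 26975 CPM in adults (SD, n = 6), a log2 fold change of 1.01 ± 0.11 (SE; edgeR adjusted p = 8.67e-06). miR-27b-3p rose 2.24-fold to 144846 ± 11161 CPM in adults (SD, n = 6), and miR-22-3p rose 2.62-fold to 56070 ± 4239 CPM. miR-10b-5p, on chromosome 3 (68113689 to 68113710, plus strand), fell 4.91-fold, from 88945 ± 43387 CPM (SD, n = 5) to 18106 ± 9803 CPM (SD, n = 6; edgeR adjusted p = 0.000231). miR-10a-5p fell 2.60-fold, from 49625 ± 16743 CPM to 19076 ± 7527 CPM. The mesenchymal marker list was lower in the same adult libraries (median log2 fold change -1.11; camera adjusted p = 0.0211, and adjusted p = 0.344 with an estimated correlation). The mean log2 CPM of that list was highest in P10 replicate 3 (9.16) and, among adults, in replicate 1 (8.49). These libraries held the most miR-10a-5p and miR-10b-5p of their age. At P10 the ranking did not hold for each member of the list. In P10 replicates 3 and 4, miR-143-3p was at 58740.5 and 45039 CPM, but miR-199a-3p was at 1241 and 1326 CPM. With the mesenchymal covariate the log2 change was -0.45 for miR-10b-5p (edgeR adjusted p = 0.611) and -0.03 for miR-10a-5p (0.953). miR-127-3p, from the imprinted Dlk1-Dio3 region, was at 95842 ± 9337 CPM at P10 and 86928 ± 6502 CPM in adults, which did not pass the test (edgeR adjusted p = 0.219). It passed as lower with library totals alone (log2 change -0.40, adjusted p = 0.00130). miR-143-3p, a smooth muscle and fibroblast miRNA, was at 41012 ± 11395 CPM at P10 and 29198 ± 15068 CPM in adults (edgeR adjusted p = 0.174). Its log2 change was -0.79 without adult replicate 1 (adjusted p = 0.00957) and -0.76 with library totals alone (0.0188), but with the mesenchymal covariate, a list that holds this miRNA, it passed as higher (1.06, adjusted p = 0.0363). Of the 10 most abundant features, 2 carried only Ensembl transcript identifiers with no name in the RefSeq table. Of these, ENSRNOT00000073699_-3p rose 1.39-fold (edgeR adjusted p = 0.00389).

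The largest rises among miRNAs above 50 CPM were those of miR-212-3p, miR-664-2-3p, miR-29b2-3p, a pair of features that overlap the miR-29 genes, and miR-384-5p. miR-212-3p, on chromosome 10 (61729163 to 61729184, plus strand), rose 4.78-fold, from 63.8 ± 8.15 CPM (SD, n = 5) to 304.4 ± 40.8 CPM (SD, n = 6; edgeR adjusted p = 1.54e-07). miR-664-2-3p rose 4.56-fold, from 30.8 ± 6.29 CPM to 139.9 ± 45.8 CPM. miR-384-5p, on chromosome X, rose 3.61-fold to 1138 ± 199 CPM in adults. miR-1843-5p rose 2.80-fold and miR-7a-1-5p 2.47-fold. The largest falls were those of miR-199a-5p, miR-181c-3p, an unnamed feature (ENSRNOT00000072773_-3p, 5.20-fold) and miR-10b-5p. miR-199a-5p, on chromosome 13 (85019427 to 85019449, plus strand), fell 6.58-fold, from 575.1 ± 31.2 CPM (SD, n = 5) to 88.1 ± 51.2 CPM (SD, n = 6; edgeR adjusted p = 6.11e-06).

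**Figure D2:**
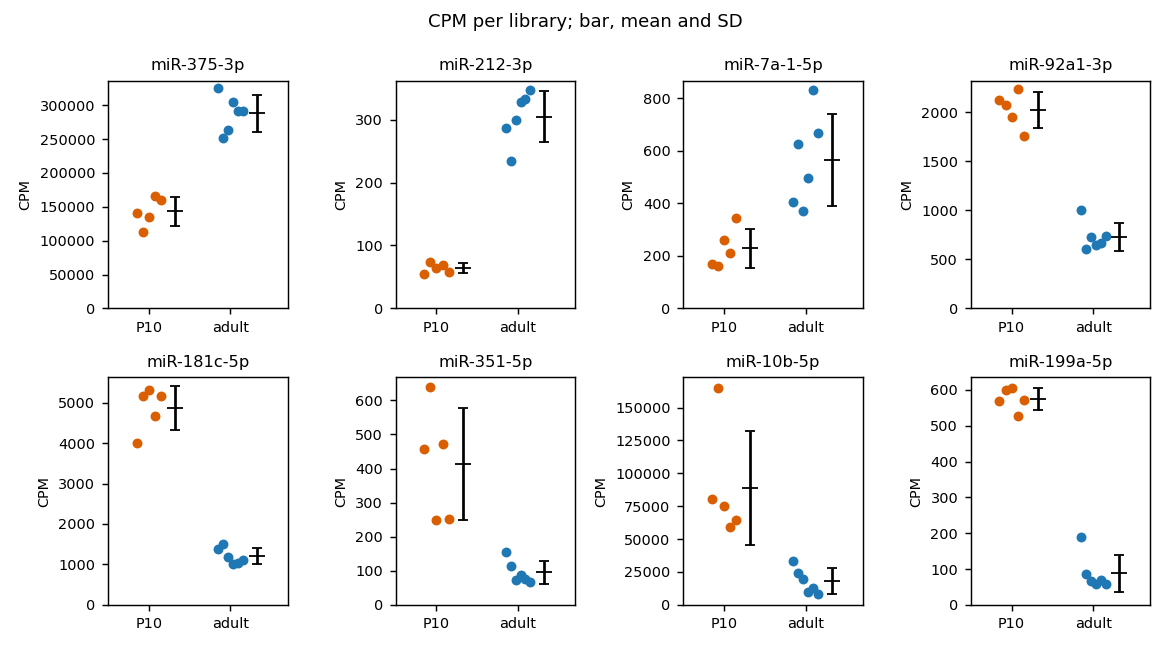
CPM (counts scaled to a TMM-adjusted library size) of 8 miRNAs in each islet library, on linear axes that start at 0. Points are libraries (P10, n = 5; adult, n = 6), and bars beside them are the mean and SD. miR-375-3p, miR-212-3p and miR-7a-1-5p were higher in adults, and miR-92a1-3p, miR-181c-5p, miR-351-5p, miR-10b-5p and miR-199a-5p were lower, with no overlap of the groups in any of the 8.

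Islet and neuroendocrine miRNAs were mostly higher in adults. Of 15 tested members of that list, 9 rose, 1 fell and 5 did not pass the test (11 and 1 when adjusted over the list alone), with a median log2 fold change of 0.77. The numbers were 5 and 1 with library totals alone, and 2 and 0 with the mesenchymal covariate (median log2 fold change 0.61). In the same adult libraries the mesenchymal list had a median of -1.11 (camera adjusted p = 0.0211, and adjusted p = 0.344 with an estimated correlation) and the acinar list a median of 1.36, which did not pass (camera adjusted p = 0.112). miR-7a-1-5p, from a family abundant in endocrine cells, rose from 228.9 ± 75.1 CPM (SD, n = 5) to 565.2 ± 176 CPM (SD, n = 6; edgeR adjusted p = 0.000762), and miR-7a-2-3p rose 2.16-fold. miR-204-5p rose 1.43-fold (edgeR adjusted p = 0.0245), a call that did not hold with library totals alone (adjusted p = 0.274), without P10 replicate 4 (0.0565) or without Ensembl-only features (0.0513, chosen after seeing the data). The member that fell was miR-184-3p, a miRNA known to target Argonaute 2, at 371.1 ± 64.1 CPM at P10 and 155.2 ± 44.6 CPM in adults; it was named after its values were seen. The camera test of the list gave an adjusted p = 0.00138, with adjusted p = 0.164 with an estimated correlation, and adjusted p = 0.0684 when a single arm of each name was kept.

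The activity-regulated neighbours miR-132 and miR-212 rose together: all 4 tested arms were higher in adults, with a median log2 fold change of 1.45. In the same adult libraries miR-375-3p was 2.01-fold higher, the mesenchymal list had a median log2 fold change of -1.11 (camera adjusted p = 0.344 with an estimated correlation), and the acinar list, which did not pass, had a median of 1.36. With the mesenchymal covariate 1 of the 4 miR-132 and miR-212 arms passed, with a median log2 fold change of 1.06. miR-132-3p rose 2.43-fold, from 197.6 ± 20.2 CPM (SD, n = 5) to 480.8 ± 98.2 CPM (SD, n = 6; edgeR adjusted p = 2.25e-05). All 4 also passed when adjusted over the list alone (camera adjusted p = 0.000664; adjusted p = 0.164 with an estimated correlation). In the miR-29 family, known for repressing collagen transcripts, 2 of 3 tested arms rose, also when adjusted over the list alone, and miR-29b1-5p did not pass (5.04 CPM in adults). Those that rose, miR-29b1-3p and miR-29b2-3p, are the same arm at 2 loci of miR-29b, so they may not be separate members. miR-29b2-3p rose 4.40-fold, to 88.3 ± 20.6 CPM in adults (SD, n = 6). With the mesenchymal covariate 0 of the 3 miR-29 arms passed, with a median log2 fold change of 1.60. The list gave a camera adjusted p = 0.0370, with adjusted p = 0.221 with an estimated correlation, adjusted p = 0.0557 without P10 replicate 5, adjusted p = 0.0555 with upper-quartile scaling and adjusted p = 0.0596 with the replicate block.

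Epithelial miR-200 family miRNAs were higher in adults in 3 of 5 tested arms (5 when adjusted over the list alone; 2 with library totals alone and 5 with upper-quartile scaling). In the same libraries the mesenchymal list had a median log2 fold change of -1.11 (camera adjusted p = 0.344 with an estimated correlation), and the acinar list, of another epithelial cell type, which did not pass, had a median of 1.36. miR-141-3p rose 1.69-fold, from 28846 ± 5868 CPM (SD, n = 5) to 48696 ± 4127 CPM (SD, n = 6), and miR-429-3p rose 1.55-fold (edgeR adjusted p = 0.00115; 0.0519 with library totals alone). The camera adjusted p = 0.0201 for this list became adjusted p = 0.262 with an estimated correlation, 0.0794 with a single arm of each name, and 0.0740 with the mesenchymal covariate. The let-7 miRNAs, regulators of developmental timing, moved little: 4 of 15 tested arms rose and 1 fell (the same numbers when adjusted over the list alone), with a median log2 fold change of 0.23, or -0.04 with library totals alone. The number that rose was 2 with library totals alone and 8 with upper-quartile scaling. let-7f-5p rose 1.76-fold and let-7i-5p fell 1.45-fold (edgeR adjusted p = 0.00133). The list's camera adjusted p = 0.0378 became adjusted p = 0.344 with an estimated correlation, and exceeded the threshold without P10 replicate 5 (0.0968), adult replicate 2 (0.0597) or adult replicate 3 (0.0579). It also did so with library totals alone (0.166), a mean CPM of at least 10 (0.0656), the replicate block (0.0676), a single arm of each name (0.137) and without Ensembl-only features (0.101).

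The proliferation-associated miR-17~92 cluster and its paralogs were lower in adults. Of 20 tested arms, 16 fell and none rose (17 fell when adjusted over the list alone), with a median log2 fold change of -1.37. miR-92a1-3p, on chromosome 15 (103641656 to 103641676, plus strand), fell 2.77-fold, from 2026 ± 183.4 CPM (SD, n = 5) to 731.2 ± 141.1 CPM (SD, n = 6; edgeR adjusted p = 1.62e-06). miR-20a-5p, from the same cluster, fell 4.73-fold from 23.6 ± 2.66 CPM, and miR-25-3p fell 1.47-fold from 2730 ± 420 CPM. The list had the smallest camera adjusted p of those tested, 2.12e-06, and adjusted p = 0.0601 with an estimated correlation. With the mesenchymal covariate 4 of the 20 arms passed, with a median log2 fold change of -0.99. The mesenchymal marker list had a median log2 fold change of -1.11 in the same libraries (camera adjusted p = 0.0211, and adjusted p = 0.344 with an estimated correlation). The leukocyte miR-150-5p fell 2.79-fold. Of the antisense features at the endothelial miR-126 gene, named after their values were seen, miR-3567-3p fell 2.24-fold and miR-3567-5p fell less (log2 change -0.75). Of the 4 leukocyte members only miR-150-5p passed (camera adjusted p = 0.538), and miR-223-3p had a log2 change of 0.72.

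Every tested arm of the miR-181 family (8 of 8) and of the X-linked miR-322 cluster, with miR-351, miR-450, miR-503 and miR-542 (7 of 7), fell, also when adjusted over the list alone. miR-181c-5p, on chromosome 19, fell 4.04-fold, from 4865 ± 539 CPM (SD, n = 5) to 1205 ± 197 CPM (SD, n = 6; edgeR adjusted p = 1.46e-07), and miR-181a-5p fell 2.05-fold to 5125 ± 1517 CPM. With the mesenchymal covariate 3 of the 8 miR-181 arms and 0 of the 7 miR-322 cluster arms passed, with median log2 fold changes of -0.83 (from -1.70) and -1.12 (from -2.01). In that fit miR-181a-5p went from -1.03 ± 0.20 to -0.11 ± 0.26 (SE; edgeR adjusted p = 0.843), and the miR-181b1 arms turned to 0.12 and 0.18 (adjusted p = 0.890 and 0.938). miR-351-5p fell 4.34-fold, from 413.3 ± 165 CPM to 95.3 ± 33.3 CPM, and miR-450a-5p fell 4.02-fold. miR-322-5p, the rat counterpart of human miR-424 and a known brake on cell-cycle genes, fell 3.00-fold from 336.5 ± 93.5 CPM (edgeR adjusted p = 0.000142). The camera adjusted p was 0.000201 for miR-181 and 0.000602 for the miR-322 cluster, with adjusted p = 0.262 and adjusted p = 0.164 with an estimated correlation. Some markers of other cell types fell in the same libraries, the mesenchymal miR-199a-5p 6.58-fold and the leukocyte miR-150-5p 2.79-fold. Antisense features at the endothelial miR-126 gene, named after their values were seen, also fell, miR-3567-3p 2.24-fold and miR-3567-5p less (log2 change -0.75). Of the 4 leukocyte members only miR-150-5p passed (camera adjusted p = 0.538), and miR-223-3p had a log2 change of 0.72. The acinar miR-217-5p rose (log2 change 1.96).

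**Figure D3:**
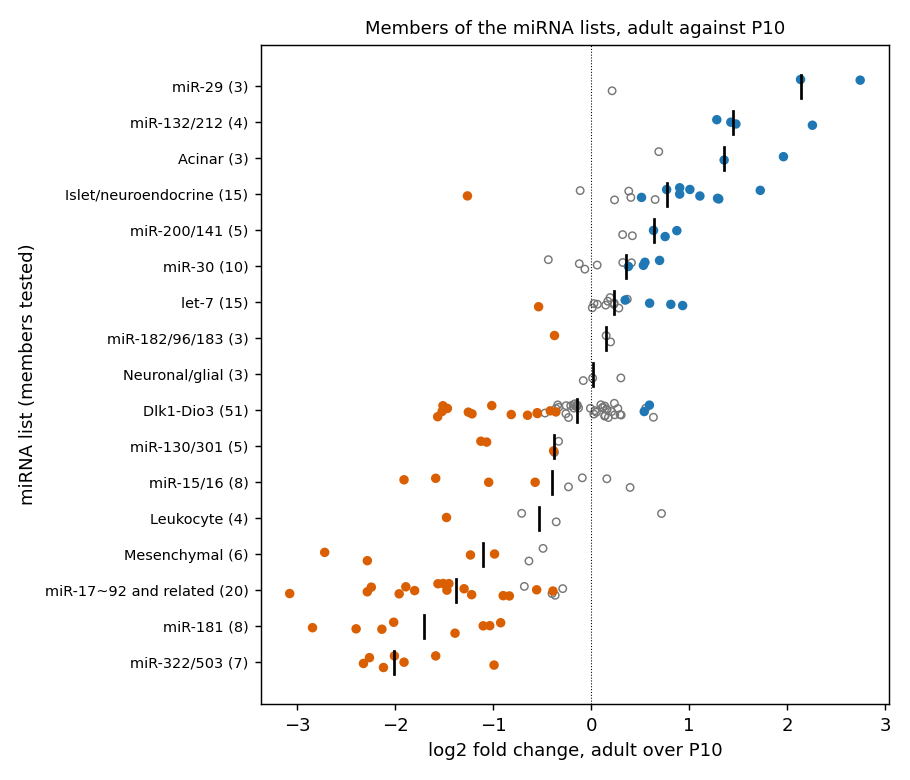
Log2 fold change (adult over P10) of the tested members of the 17 miRNA lists with at least 3 tested members, sorted by median (black bars). Filled points passed edgeR's test at an adjusted p under 0.05 (blue higher, orange lower in adults), and open points did not. The miR-17~92, miR-181 and miR-322 cluster lists lie to the left of 0 and the miR-132 and miR-212 list to the right.

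The other program lists did not pass the camera test. In the imprinted Dlk1-Dio3 cluster 13 of 51 tested arms fell, 2 rose and 36 did not pass (10 and 0 over the list alone, camera adjusted p = 0.406), against 20 that fell and 0 that rose with library totals alone. With the mesenchymal covariate this list passed as lower (camera adjusted p = 0.000257). miR-412-5p fell 2.85-fold and miR-431-5p fell 1.57-fold, while miR-541-5p was at 3542 ± 940 CPM at P10 (SD, n = 5) and 3853 ± 421 CPM in adults (SD, n = 6). In the miR-15/16 list 4 of 8 arms fell, including the 2 miR-322 arms it shares with the miR-322 cluster list (4 over the list alone, camera adjusted p = 0.235), and miR-16-5p did not pass the test (7672 ± 702 CPM in adults). In the miR-130 and miR-301 list 3 of 5 fell, also over the list alone (camera adjusted p = 0.0973), among them miR-130a-3p, 2.09-fold. This list passed without P10 replicate 1 (0.0411). In the miR-30 list 4 of 10 rose (3 over the list alone, camera adjusted p = 0.113), led by miR-30d-5p at 22517 ± 1812 CPM in adults. Of the miR-30 arms, 2 were higher and 2 lower with library totals alone (mean log2 fold change -0.03, against 0.23), and 6 were higher with upper-quartile scaling. The miR-30 list passed with the mesenchymal covariate (camera adjusted p = 0.0409). The miR-30, miR-130 and acinar lists passed with no filter (0.0288). In the list of miR-182, miR-96 and miR-183, 1 of 3 fell, also over the list alone (camera adjusted p = 0.819), with a median log2 fold change of 0.15 and a mean of -0.01. That member, miR-183-5p (8217 ± 1643 CPM at P10, 6309 ± 510 CPM in adults), did not pass with DESeq2's size factors (edgeR adjusted p = 0.0652), upper-quartile scaling (0.199) or DESeq2 (adjusted p = 0.0590). Of the miR-34 and miR-449 list, miR-34c-5p fell 2.45-fold (edgeR adjusted p = 8.62e-06) and miR-34a-5p did not pass, except as lower after thinning (log2 change -0.56, adjusted p = 0.0437), with no list test for 2 members. No miRNA of the miR-483 and miR-675 list passed the abundance filter.

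Markers of other cell types moved with age in several cases. In the mesenchymal list 4 of 6 arms fell, also over the list alone: miR-199a-3p fell 4.86-fold, from 1237 ± 59.6 CPM (SD, n = 5) to 255.2 ± 154 CPM (SD, n = 6), and miR-145-5p, which was named after its values were seen, fell 2.35-fold. The list's camera adjusted p = 0.0211 became adjusted p = 0.344 with an estimated correlation and 0.103 with a single arm of each name. Of the acinar list, miR-217-5p rose 3.90-fold, from 9.68 ± 2.03 CPM to 38.5 ± 20.6 CPM (edgeR adjusted p = 0.000805), and miR-216a-5p rose 2.56-fold. The latter call ended without P10 replicate 1 (adjusted p = 0.05999), adult replicate 3 (0.0541) or adult replicate 6 (0.0640), with library totals alone (0.0542), and with limma-voom (0.107). These 2 of 3 acinar members also passed over the list alone (camera adjusted p = 0.112), against 1 with library totals alone and 3 with upper-quartile scaling. Of the leukocyte list, miR-150-5p fell 2.79-fold, from 367.4 ± 163 CPM to 131.6 ± 51.0 CPM, 1 of 4 members also over the list alone (camera adjusted p = 0.538), and miR-142-5p and miR-223-3p did not pass. With library totals alone 3 of the 4 were lower, among them miR-142-5p (log2 change -0.97, adjusted p = 0.0488). miR-223-3p passed as higher with upper-quartile scaling (adjusted p = 0.0449), DESeq2 (0.0422), the mesenchymal covariate (0.0204) and without adult replicate 5 (0.0263). None of the 3 tested members of the neuronal and glial list passed (0 over the list alone, camera adjusted p = 0.738), with miR-128-3p at 114 ± 20.2 CPM in adults. miR-128-3p passed as higher with upper-quartile scaling (adjusted p = 0.0305), DESeq2 (0.0370) and without adult replicate 2 (0.0350). Neither of the 2 erythroid members passed, with miR-451-5p at 35.2 ± 19.5 CPM at P10 and 28.2 ± 14.98 CPM in adults. No endothelial, hepatocyte or muscle list member passed the filter under its own name.

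Both arms of a precursor did not always follow age alike. Of 145 precursors with both arms tested, the ratio of 5p to 3p reads was higher in adults for 20 and lower for 17 (limma on log2 ratios, Benjamini-Hochberg adjusted). These numbers include features tagged antisense, whose arms are named from the other strand. Their direction would be reversed if the reads belong to the overlapping gene. For miR-181a the log2 ratio rose by 1.67 ± 0.17 (SE; limma adjusted p = 1.54e-05), as miR-181a-3p fell 7.17-fold and miR-181a-5p 2.05-fold. For miR-24 it changed by -1.62 ± 0.20 (SE, limma adjusted p = 4.97e-05): miR-24-5p fell 1.71-fold, to 118.5 ± 26.4 CPM, while miR-24-3p rose 1.77-fold, to 558.7 ± 84.4 CPM. A feature outside the rule, miR-3074, counted antisense and overlapping Mir24-1, did not pass (0.40 ± 0.27, SE, limma adjusted p = 0.283). Its arms are named from the other strand. For miR-152 the change was -1.51 ± 0.22 (SE; limma adjusted p = 0.000256), with miR-152-5p down 1.57-fold and miR-152-3p up 1.80-fold. The feature named miR-3581, counted antisense and overlapping Mir409, changed by 1.12 ± 0.18 (SE, limma adjusted p = 0.000515). Its arms too are named from the other strand, so for Mir409 the change would be a fall of 5p against 3p. For miR-29b1 the change was -2.07 ± 0.33 (SE; limma adjusted p = 0.000515), with arms at only 5.04 and 7.86 CPM in adults. Several of these arms have the same sequence at more than 1 locus, which limits how reads can be assigned to a precursor.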

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

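A library was flagged where its CPM lay far from the nearest other library of its age, by Dixon's criterion on the gap over the range. Of 144 tests 14 passed, where chance alone gives about 1 in 20, or 7.2.

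Adult replicate 1 stood above the other adult libraries for 6 features. It held 57172 CPM of miR-143-3p (next library 31127), 190.4 CPM of miR-199a-5p (next 86.7), 559.5 CPM of miR-199a-3p (next 244.7) and 173.5 CPM of ENSRNOT00000072773_-3p (next 69.5). It also held 139.7 CPM of miR-181d-5p (next 88.9) and 1000.4 CPM of miR-92a1-3p (next 737). For each feature that passed the age test, this library still lay below all P10 libraries.

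P10 replicate 3 stood apart for 4 features. It held 165089 CPM of miR-10b-5p (next library 80321), 78684 CPM of miR-10a-5p (next 46976) and 600.1 CPM of miR-181d-5p (next 367.4). It held only 646.5 CPM of the antisense feature at the miR-29a gene, miR-3556a-5p (next 1008).

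P10 replicate 1 held 2888 CPM of let-7f-5p (next 3766) and 69.0 CPM of the erythroid miR-451-5p (next 34.1). Adult replicate 3 held 166569 CPM of miR-27b-3p (next 143922), and adult replicate 2 held 73.3 CPM of miR-128-3p (next 115.3). No biological explanation was tested for these single libraries.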

How the results depend on the processing

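The mesenchymal covariate, thinning, leaving out Ensembl-only features and naming antisense features by gene, also with an estimated correlation, were chosen after seeing the data. Over the planned fits with all 11 libraries, 201 to 248 miRNAs passed against 232, and when a library was left out 197 to 230 passed. No miRNA called in the main comparison was called in the opposite direction in any alternative. With library totals alone 54 miRNAs were higher in adults, against 97. With the mesenchymal covariate 33 passed (19 higher, 14 lower), 27 of them among the 232. The covariate correlates with age at -0.87. Of the 205 calls that ended, 145 kept at least 50% of their log2 change (miR-141-3p went from 0.76 ± 0.13 to 0.75 ± 0.27, SE), so a larger SE ended calls as well as smaller changes. Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.21 to 0.20 and 0 of 5 P10 libraries correlated best with their own number. With the replicate block 205 miRNAs, 7 lists and 37 precursors passed, 199 of the miRNAs among the 232, and the let-7 and miR-29 lists did not (adjusted p = 0.0676 and 0.0596). The number of lists called, 9, was 0 with camera at an estimated correlation (4 at an unadjusted p under 0.05), 0 also with antisense features named by gene at an estimated correlation, 14 with fry, which does not compare a list with other miRNAs, and 3 when a single arm of each name was kept. With a single arm 4 of the 9 lists no longer passed, and the miR-29 and miR-132 and miR-212 lists, with fewer than 3 members, were not tested. With no filter the miR-30, miR-130 and acinar lists also passed (adjusted p = 0.0288). Thinning left 214 miRNAs and 8 lists. Leaving out each library kept the arm usage count between 32 and 44 and the miR-375-3p share difference between 9.15 and 11.3 percentage points.

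The let-7 list, which passed in the main comparison, kept its camera direction, but with library totals alone its median turned to -0.0407 and its mean to -0.00807. With the mesenchymal covariate 11 of the 232 calls changed direction. Among them, outside the naming rule, were miR-181b1-5p (0.12), miR-181b1-3p (0.18) and miR-145-5p (0.05), with edgeR adjusted p of 0.890, 0.938 and 0.953. miR-145-5p, like miR-143-3p, belongs to the list that gave the covariate, so its change in that fit is not independent of it. For miRNAs named by the rule, and for camera directions of lists, the other changes of sign involved ones that did not pass in the main comparison. let-7c-1-5p and that Ensembl-only feature of the 10 most abundant which did not pass in the main comparison passed as higher with DESeq2's size factors (adjusted p = 0.0195 and 0.0295), upper-quartile scaling (0.00834 and 0.0224) and DESeq2 (0.00561 and 0.0195), the former also without P10 replicate 1 (0.0194) or adult replicate 5 (0.0359), and the latter without P10 replicate 6 (0.0491). With library totals alone log2 changes were -0.00316 for the Ensembl-only feature of the 10 most abundant that did not pass, -0.0339 for let-7c-1-5p, -0.0866 for miR-16-5p, -0.12 for miR-541-5p, -0.0433 for miR-29b1-5p, -0.0966 for miR-96-5p, -0.0657 for miR-183-3p, -0.15 for miR-144-5p and -0.23 for miR-128-2-3p, and the miR-182, miR-96 and miR-183 list turned (adjusted p = 0.841). With upper-quartile scaling miR-127-3p was at 0.0231 and miR-128-5p at 0.0845. miR-128-5p was at 0.0152 with DESeq2's size factors and 0.0167 with DESeq2, and at 0.00834 after thinning. miR-128-2-3p was at -0.0205 with a mean CPM of at least 10 and -0.0545 without Ensembl-only features, and miR-144-5p at -0.21 with the replicate block. With no filter the neuronal and glial list turned (adjusted p = 0.949). With the mesenchymal covariate miR-143-3p was at 1.06 (adjusted p = 0.0363, passing as higher), miR-142-5p at 0.30 and miR-128-2-3p at -0.79, and the lists miR-15/16 (0.791), miR-182, miR-96 and miR-183 (0.939), leukocyte (0.236) and neuronal and glial (0.270) turned. Leaving out a library gave ranges of -0.00402 to 0.35 for miR-16-5p, -0.0261 to 0.21 for miR-541-5p, -0.60 to 0.0725 for miR-451-5p, -0.28 to 0.30 for miR-144-5p, -0.0763 to 0.12 for miR-128-2-3p and -0.22 to 0.0117 for miR-128-5p. The cause was not tested. Depth limits miRNAs of a few CPM most.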

Other observations

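The tests of scaling, of the miR-375-3p ratio and of the antisense counts were chosen after their results were seen, as were the thinned and covariate fits.

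Some abundant features of the islet libraries carried an antisense tag. Of 106 features counted antisense, 74 overlap another RefSeq miRNA gene, 21 do not and 11 could not be looked up. The 74 include features at the miR-126, miR-214, miR-29a, miR-29c, let-7f-1 and miR-200a genes, named here after their values were seen. Of the features at the endothelial miR-126 gene, miR-3567-3p fell 2.24-fold, from 5992 ± 2092 CPM (SD, n = 5) to 2681 ± 487 CPM (SD, n = 6, edgeR adjusted p = 0.000625). The other, miR-3567-5p, fell less, from 1966 ± 391 CPM to 1172 ± 152 CPM (log2 change -0.75, edgeR adjusted p = 0.000669). The feature at miR-214 (miR-3120-5p), a mesenchymal gene, fell 8.46-fold from 92.02 ± 12.5 CPM. The feature at let-7f-1 (miR-3596d-3p) rose 1.85-fold to 14143 ± 1686 CPM, and that at miR-29a (miR-3556a-5p) rose 4.04-fold, to 3880 ± 426 CPM. With these features named by the overlapping gene, 5 of 6 miR-29 members rose (camera adjusted p = 0.000464; adjusted p = 0.131 with an estimated correlation). By the same naming 5 of 9 miR-200 members rose, 6 of 8 mesenchymal members fell, and 2 of 2 endothelial members fell.

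Other splits of the 11 libraries into 5 and 6 tested whether the sample grouping alone gives such counts. Of 100 splits drawn from 462, with the real one, only the real one gave as many as 232 miRNAs, the highest of the others being 186. With 100 splits the smallest share such a test can give is 1 in 100. A split that mixes the ages holds the age difference within its groups, so its low count is no separate support. For arm usage 1 split gave as many as 37 precursors, the highest of the others being 27. The splits that came close kept the 5 P10 libraries together with 1 adult library added. Splits that parted the P10 libraries gave 0 miRNAs with edgeR (at most 137 at an unadjusted p under 0.05, against 261) and at most 4 precursors. For the list tests chance is not excluded: 9 of 100 splits gave at least the 9 lists called by age, with a highest other count of 10, and 5 of these parted the P10 libraries. The number of lists called with the preset correlation therefore carries little weight beside the counts of members.

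Lower miR-17~92, miR-181 and miR-322 cluster miRNAs in adult islets were set against 3 technical explanations, for 31 members with a median log2 fold change of -1.58, at a distance of -1.47 from the median of all miRNAs. Scaling to a few abundant miRNAs is argued against: over 5 scalings the median of all 35 tested members ran from -1.78 to -1.35, with 30 to 34 lower and 0 higher, while 54 to 127 of all miRNAs were higher. For the lower depth of adult libraries, thinning left a distance of -1.63, so the difference was also present at equal totals. Thinning keeps expected shares and could hardly remove the distance of members chosen because they were called lower. No conclusion on depth is drawn from it. A smaller share of mesenchymal cells in adult preparations cannot be told apart from age: with the mesenchymal covariate the median was -1.12 and 7 of 31 members passed, but the covariate correlates with age at -0.87. Fewer leukocytes or endothelial cells were not tested and stay open, as does a change within endocrine cells with age, which the design names. The former were read from miR-150-5p (2.79-fold lower) and the antisense features at miR-126 (miR-3567-3p 2.24-fold lower, miR-3567-5p at a log2 change of -0.75). The other tested leukocyte members did not pass, and miR-223-3p had a log2 change of 0.72 (edgeR adjusted p = 0.101).

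Higher miR-132 and miR-212 and miR-29 miRNAs in adult islets were set against 2 technical explanations. For the 4 miR-132 and miR-212 arms a larger share of endocrine cells, as read from miR-375-3p, cannot be told apart from age: the log2 ratio to miR-375-3p had a median change of 0.40, and it passed for miR-212-3p (1.22) but not for miR-132-3p (0.24 ± 0.21, SE; limma adjusted p = 0.274), miR-132-5p (0.39; 0.109) or miR-212-5p (0.41; 0.109). For the set of 6 miR-29 features, 3 of them antisense, the ratio had a median change of 1.03, and 4 passed as higher. The 4 include miR-29b1-3p and miR-29b2-3p, the same arm at 2 loci of miR-29b. The ratio did not pass for miR-3556b-3p (-0.18, limma adjusted p = 0.419) and fell for miR-29b1-5p (-0.96, limma adjusted p = 0.00158). These ratios restate fold changes that had been seen. They bear on the endocrine share only if miR-375-3p per endocrine cell did not change with age, which was not tested. A change in acinar cells, whose list had a median log2 fold change of 1.36 and did not pass, was not tested either. The endocrine share therefore stays open for miR-29 too. For lower depth, after thinning the members lay 1.82 above the median of all miRNAs, so the difference was also present at equal totals. As thinning keeps expected shares, it could hardly remove that difference, and no conclusion on depth is drawn from it. An age effect in the islet cells is a candidate explanation that these data leave open.

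Counts antisense to annotated miRNAs were set against a mapping and a strand explanation, with no biological explanation tested. Of the 95 antisense features found in the RefSeq table, all 51 with a mean of 10 or more counts overlap another RefSeq miRNA gene, and 0 of them overlap none, against 21 of 44 others (Fisher's exact test, two-sided, p = 3.29e-09). This is consistent with reads of an overlapping miRNA gene on the other strand. Strand errors that copy a share of the sense reads are argued against, since miR-375-3p, with the most sense reads, had 0.176 antisense reads per 1000000 sense reads. The value of a feature tagged antisense may thus belong to the overlapping gene, a hypothesis found and tested on the same counts. Fisher's test counted both arms of a precursor as separate features though they share the overlap, so its p-value is too small.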
